A study of Homo sapiens with 9 samples.

How the data were processed

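RNA was measured on 9 Affymetrix gene arrays of cultured human breast cells. MCF-7 is an oestrogen receptor positive breast cancer line and gave 8 arrays. MCF-12A is a line made from non-malignant breast epithelium and gave 1 array. Per the labels, ethanol was given to MCF-7 at 25 mM for 1 week (1 array) or for 4 weeks (2 arrays), and acetaldehyde at 2.5 mM for 1 week (1 array). Untreated MCF-7 gave 4 arrays: 1 named as the control of the 1-week experiment, 1 for each of the numbered 4-week experiments, and 1 named as the control for the ratio to MCF-12A, called the ratio control here. The labels do not say which control belongs to the acetaldehyde array, and MCF-12A was grown by its supplier's directions, so medium and line differ together. The labels do not say whether replicates were separate cultures, so every p-value measures the spread between these arrays alone, which can be technical.

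The deposited values are linear probe set intensity. How the authors summarised and normalized them is not given in the sources used here. Median intensity per array ranged from 77.8 to 162.5, so the arrays had not been brought to 1 distribution. Compared to every deposited decimal, identical values at the same probe set occurred only within 4 sets of arrays. The 4-week pair of experiment 1 shared 731 such probe sets, the pair of experiment 2 shared 949, and the 1-week control and 1-week ethanol arrays shared 50. The MCF-12A, ratio control and acetaldehyde arrays formed the remaining set, with 55, 37 and 54 shared probe sets in their 3 pairs. Every pair of arrays from different sets shared 0. These 4 sets were taken as arrays processed together, which is read from the values and not stated by the labels.

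By a rule fixed in advance for arrays whose medians differ, values were quantile normalized over the 9 arrays and transformed as log2(intensity + 16). The added 16 understates changes of dim genes. Probe sets were tested when their mean log2 value over the arrays of a comparison lay above the median of all probe sets (the 50th percentile). Control probe sets of the array maker could not be identified from the annotation used and were not removed. The number of arrays limits the precision of every value.

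The array has 33297 probe sets. Of these, 21214 were listed with a gene, 19460 with 1 symbol and 1754 with several, and 12083 with none. Symbols were updated through gene identifiers in a RefSeq table of the GRCh38.p14 assembly, used for names only, which covered 19429 probe sets and left 18417 distinct symbols, 769 of them with several probe sets. POU5F1 and NANOG lie only on probe sets shared with other genes and have no value here.

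Tests used limma 3.58.1 in R 4.3.3 with an intensity trend in the empirical Bayes step, and Benjamini-Hochberg adjusted p below 0.05. Ethanol and control at 4 weeks were compared as 2 arrays against 2. All 3 ethanol experiments were compared with their controls with experiment as a term. The ethanol effect at 4 weeks minus that at 1 week was tested as an interaction. MCF-12A was compared with the 4 untreated MCF-7 arrays, and its lone array was assumed to vary as they do. Single arrays were compared by the number of probe sets with an absolute log2 ratio of at least 1 (2-fold), and also tested in a model of all 8 MCF-7 arrays whose spread comes from the 4-week pairs alone.

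Gene lists written in advance (24) were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the lists. Each gene was represented by its brightest probe set. Genes of a list count as measured where that probe set passed the intensity filter, so dim genes are left out of medians and shares. For single arrays, a list's median log2 ratio was placed among those of 10000 random lists matched for intensity in 20 bins, which gives a percentile and no p-value. Named genes were chosen by a rule. With at least 20 probe sets past the threshold, they were the 10 highest and 10 lowest changes among those. With fewer, they were the 10 smallest p in each direction with 1 sign in every experiment. Single comparisons gave the 10 highest and 10 lowest ratios. Up to 4 members of each list with the smallest p or largest ratio were added, with a short fixed set of receptor, alcohol metabolism and cell type genes. The text names a part of these, for a shorter text. Genes quoted again for another comparison, to set values side by side, are outside the rule.

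The tests were tried on simulated arrays with 100 probe sets changed by 1 log2 unit and 100 changed by 2. For ethanol at 4 weeks, run on 16646 probe sets, 12 and 87 were called, with 6 unchanged probe sets. For the 3 experiments, run on 16648, 91 and 99 were called, with 8 unchanged ones. For the interaction and for 1-week acetaldehyde, each run on 16648, 0 were called at either size. For MCF-12A, run on 16647, 0 and 8 were called, with 1 unchanged probe set. In each of these 5 simulations a list shifted by 0.5 was called at the preset correlation, and 0 of the other 23 lists. The simulated genes varied independently of each other. In the real arrays the estimated correlation reached values such as 0.57 for the unfolded protein list at 4 weeks. The simulation therefore cannot tell how often correlated lists are called without an effect.

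The experiment number in the labels pairs the 4-week arrays, and the pairing correlation within experiments was 0.598. Comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were the deposited scale, median centring, pseudocounts of 1 and 64, no filter and a filter at the 70th percentile, no trend or a robust trend, the experiment as a replicate block, other control arrays, a 1.5-fold size and leaving out each array. Chosen after the data were seen were the ratio control as the control of the acetaldehyde array, probe sets listed with a gene alone, and tests between untreated arrays.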

Results

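The data are probe set intensities of MCF-7 breast cancer cells grown with or without ethanol or acetaldehyde, and of the non-malignant line MCF-12A. The 9 arrays fall into untreated MCF-7 (4), ethanol for 1 week (1) and for 4 weeks (2), acetaldehyde for 1 week (1) and MCF-12A (1). Median intensity per array ran from 77.8 in the untreated array of 4-week experiment 1 to 162.5 in the 1-week control. Between MCF-7 arrays, the lowest mean correlation with the others was 0.961, for the 1-week control. Errors are standard errors of the limma fit, and comparisons of single arrays have no replicates.

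The first question is which genes differ in MCF-7 after 4 weeks in 25 mM ethanol. Interferon-induced genes were higher with ethanol in both experiments. Genes of the unfolded protein response were higher and genes of cell division lower, mostly in experiment 1. The prostaglandin-degrading enzyme HPGD was lower in both. No single gene passed the test across all probe sets, so these are differences of groups of genes and of the genes with the smallest p.

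In the interferon response list, 21 of 23 measured genes were higher with ethanol, with a median log2 fold change of 0.44. The list passed at the preset correlation (adjusted p = 3.5e-22) and not otherwise (adjusted p = 0.42 with an estimated correlation). In this list 8 genes were higher when adjusted over the list alone, against 0 over all probe sets. With the experiment as a replicate block, 13 were higher adjusted over the list alone. IFI6, an interferon-induced gene with a mitochondrial product, had a log2 fold change of 2.58 ± 0.35 (n = 2 arrays per group, limma), 3.19 in experiment 1 and 1.96 in experiment 2. SAMD9, a restriction factor for viruses, was 1.81 ± 0.21 higher, with 2.00 and 1.62 in the experiments. OAS1, which senses double-stranded RNA, was 1.26 ± 0.25 higher. PARP9 (0.76 ± 0.15) and PARP14 (0.82 ± 0.16), ADP-ribosyltransferases of the interferon response, and the RNA-binding IFIT5 (0.80 ± 0.19) went the same way. Outside the list, complement factor CFB was 1.38 ± 0.26 higher and the chemokine CCL22 1.10 ± 0.22 higher. The genes with the smallest p among those lower were HPGD (-0.99 ± 0.18), the fatty acid elongase ELOVL2 (-0.76 ± 0.19) and the histone gene H2AC12 (-0.61 ± 0.17). In the 19 interferon genes measured above the filter of the MCF-7 arrays, the median log2 ratio was 0.24 in experiment 1 and 0.26 in experiment 2. Both medians lay at the 100th percentile of random lists, as did the unfolded protein, stem cell and hypoxia lists in experiment 1 and the basal and p53 lists in experiment 2.

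**Figure D1:**
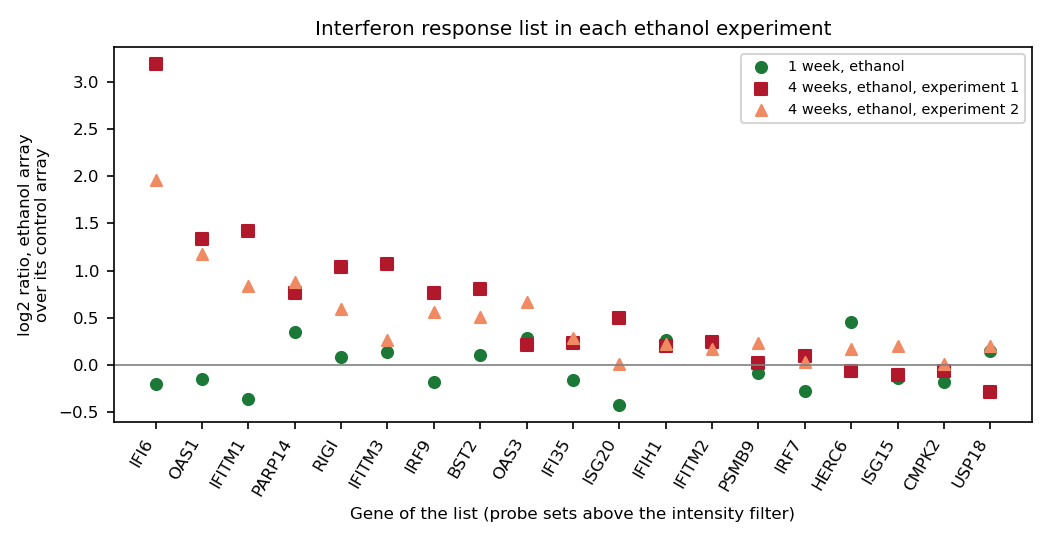
Log2 ratio of ethanol array over control array (vertical axis) for each gene of the interferon response list above the intensity filter (horizontal axis), with 1 point per experiment. In 4-week experiment 2 all 19 genes lie above 0, in 4-week experiment 1 15 of 19 do, and IFI6 stands highest at 3.19 and 1.96.

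Secretory stress and growth genes moved mostly in experiment 1. The unfolded protein and amino acid response list had a median of 0.52 with 28 of 29 genes higher (adjusted p = 1.3e-15; adjusted p = 0.42 with an estimated correlation). Its median was 1.02 in experiment 1 and 0.05 in experiment 2. The chaperone HSPA5 was 0.83 ± 0.24 higher, with 1.33 and 0.34 in the experiments, and MANF, which is secreted under such stress, 0.77 ± 0.28 higher. The proliferation list had a median of -0.49 with 38 of 39 genes lower (adjusted p = 7.8e-24; adjusted p = 0.42 with an estimated correlation), from -0.85 in experiment 1 and -0.13 in experiment 2. The cyclin CCNA2 was -0.75 ± 0.29, the survivin gene BIRC5 -0.62 ± 0.23 and the mitotic kinase AURKA -0.64 ± 0.26. In the cholesterol and lipid synthesis list all 22 genes were lower, with a median of -0.26 (adjusted p = 3.3e-07; adjusted p = 0.44 with an estimated correlation), from -0.59 and 0.01 in the experiments. Its members IDI1 (-0.74 ± 0.37) and SCD (-0.64 ± 0.34) make isoprenoid precursors and unsaturated fatty acids. The p53 targets list had a median of 0.12 (adjusted p = 8.8e-05; adjusted p = 0.42 with an estimated correlation), and 0.15 and 0.16 in the experiments. TP53INP1, a p53 cofactor, was 1.02 ± 0.31 higher, and the stress cytokine GDF15 1.48 ± 0.65 higher, with 2.60 and 0.37 in the experiments. The hypoxia and glycolysis list had a median of 0.16 (adjusted p = 1.9e-04; adjusted p = 0.44 with an estimated correlation), from 0.41 and -0.05, and NDRG1, a hypoxia-induced gene, stood at 2.12 and 0.06. Leaving out the control of experiment 1 took the median of the unfolded protein list to 0.06 and that of the cholesterol list to -0.02, and both calls were lost. The hypoxia call was lost without the control of experiment 1 (median 0.09) and without its ethanol array (median 0.14).

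Lists of cell identity stood higher as well. The median was 0.13 for luminal markers (0.22 and 0.08 in experiments 1 and 2) and 0.25 for basal and myoepithelial markers (0.30 and 0.19). It was 0.24 for stem cell genes (0.39 and 0.08) and 0.20 for metalloproteinases and their inhibitors (0.33 and 0.06). Each of these lists was called by camera at the preset correlation, with adjusted p = 0.42 with an estimated correlation. Epithelial junction genes had a median of 0.13 (adjusted p = 6.7e-04, and adjusted p = 0.44 with an estimated correlation), from 0.26 and 0.08 in the experiments. TIMP2, an inhibitor of matrix metalloproteinases, was 0.60 ± 0.21 higher. Without the control of experiment 1 the luminal (0.065), junction (0.0085) and metalloproteinase (0.16) calls were lost, and without the ethanol array of experiment 1 the basal (0.17) and stem cell (0.006) calls. The stem cell call was also lost without the control of experiment 2 (0.17) and the junction call without its ethanol array (0.13). ESR1, the oestrogen receptor gene, had a log2 fold change of -0.06 ± 0.20 and its target TFF1 0.10 ± 0.38, and both changed sign when 1 array was left out (ESR1 to 0.065 and TFF1 to -0.41 without the control of experiment 1). The progesterone receptor gene PGR was 0.77 ± 0.29 higher, with 1.25 and 0.29 in the experiments. Its SD over the 4 untreated MCF-7 arrays, which come from different processing sets, was 1.37. The oestrogen target list had a median of 0.10 (adjusted p = 0.17), and -0.027 without the control of experiment 1. The ethanol and aldehyde metabolism list stood at 0.06 (adjusted p = 0.12), and ADH5, the formaldehyde and alcohol dehydrogenase expressed in most cells, at -0.03 ± 0.19.

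In the limma test of ethanol at 4 weeks, 0 of 16646 probe sets passed, and every gene named for it had an adjusted p of 1. At an unadjusted p under 0.05 there were 188 probe sets, 120 higher and 68 lower, against 832 that chance gives. That fit had no term for experiment, although the labels pair the arrays. Its spread and standard errors thus include the difference between the experiments, so the shortfall does not show that ethanol had no effect. Leaving out 1 array changed the count: 332 probe sets passed without the control of experiment 2 and 9 without the control of experiment 1, and 0 without either ethanol array. In such fits the spread comes from the group that keeps its arrays, so these counts do not measure robustness. Without the control of experiment 2 and without that of experiment 1, the log2 fold change of IFI6 was 3.06 and 2.09. That of SAMD9 was 2.08 and 1.54. Of 24 lists, 17 were called at the preset correlation, 0 with an estimated correlation and 0 by fry. The interferon, proliferation and p53 lists were called with any 1 of the 4 arrays left out.

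With the 1-week experiment added, the question is which differences hold over 3 experiments. In the joint fit interferon-response genes were higher and cell division and cholesterol synthesis genes lower. The interferon group rests on both 4-week experiments, and the cell division and cholesterol groups mostly on 4-week experiment 1. At 4 weeks the proliferation list had medians of -0.85 in experiment 1 and -0.13 in experiment 2. At 1 week the interferon list had a median of -0.09 with 9 of 19 genes higher, and the proliferation list 0.05 with 27 of 39 higher. The cholesterol list had medians of -0.09 at 1 week, with 5 of 22 genes higher, and of -0.59 and 0.01 in the 4-week experiments. With median centring its 1-week median was 0.02. PARP14 and its partner DTX3L, a ubiquitin ligase, were higher in each experiment. PARP14 had log2 ratios of 0.35 at 1 week and 0.76 and 0.88 at 4 weeks, a fitted change of 0.66 ± 0.12 (n = 3 pairs). DTX3L was 0.53 ± 0.10 higher and SAMHD1, a nucleotide hydrolase that restricts viruses, 0.44 ± 0.09 higher. The histone gene H3C12 was -0.76 ± 0.15, TPT1, the translationally controlled tumour protein gene, -0.53 ± 0.13, and the fructose kinase gene KHK -0.39 ± 0.11. The probe set of TPT1 had low intensity, with a mean log2 value of 7.23 in the untreated MCF-7 arrays. The interferon list had a median of 0.23 (16 of 19 higher; adjusted p = 7.0e-08; 1 gene adjusted over the list alone), the proliferation list -0.28 (38 of 39 lower; adjusted p = 9.8e-12), and the cholesterol list -0.20 (23 of 23 lower; adjusted p = 5.5e-08). The unfolded protein list had a median of 0.35 (adjusted p = 4.1e-08) and the metallothioneins, metal-binding stress proteins, 0.26 (adjusted p = 9.7e-04). Each of these 5 lists had an adjusted p of 0.56 with an estimated correlation. The limma test passed 0 of 16648 probe sets, with 520 at an unadjusted p under 0.05 (379 higher, 141 lower) and a smallest adjusted p of 0.923, and fry called 0 lists. Without 4-week experiment 1, 10 probe sets passed, the unfolded protein median was -0.01, the proliferation median -0.03 and the cholesterol median -0.04, and these 3 calls were lost. Without the 1-week experiment the metallothionein median was 0.08 and its call was lost. The interferon list was called with any 1 experiment left out.

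**Figure D2:**
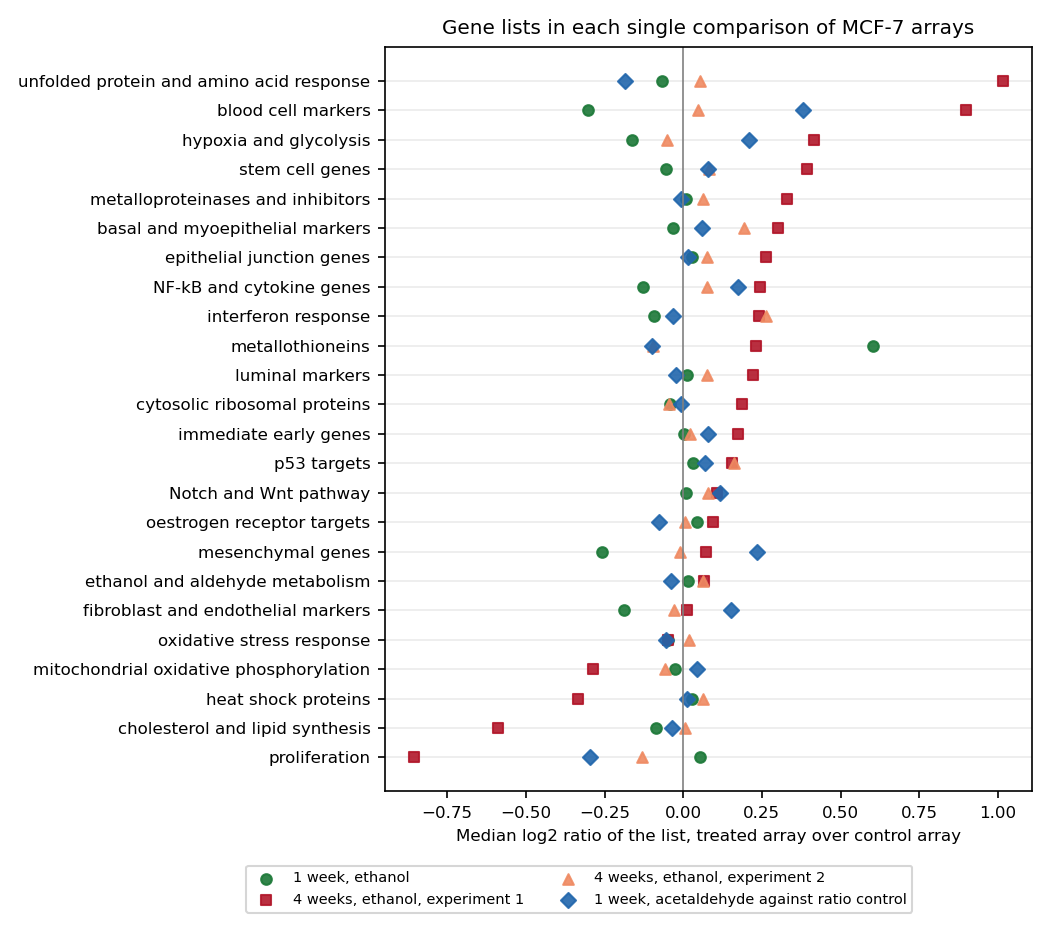
Median log2 ratio of treated array over control array (horizontal axis) for each gene list (vertical axis), with 1 point per comparison of single MCF-7 arrays. The unfolded protein list stands at 1.02 and the proliferation list at -0.85 in 4-week experiment 1, and at 0.05 and -0.13 in 4-week experiment 2.

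After 1 week in ethanol, metallothionein genes stood out. MT1X had a log2 ratio of 1.36, MT1F 1.10, MT2A 0.94 (0.89 on its brightest probe set, used for the lists and in the other comparisons) and MT1G 0.70. The metallothionein list had a median of 0.60 with 8 of 9 genes higher, at the 100th percentile of random lists. MAT2A, which makes S-adenosylmethionine, was 0.77 higher. CYP1A1, a target of the aryl hydrocarbon receptor, was at -0.91, H3C12 at -0.86 and TPT1 at -0.77. The probe sets of CYP1A1 and TPT1 had low intensity (mean log2 6.96 and 7.23 in the untreated MCF-7 arrays). The hypoxia and glycolysis list had a median of -0.16 with 1 of 25 genes higher, with P4HA1, a collagen prolyl hydroxylase, at -0.31. The mesenchymal list had a median of -0.26 with 1 of 9 higher. Markers of other cell types stood lower too, with 0 of 4 fibroblast and endothelial markers higher (median -0.19) and 0 of 2 blood cell markers (-0.30). The medians of the metallothionein, hypoxia and mesenchymal lists kept their sign on the deposited scale and with median centring, but the hypoxia median shrank to -0.099 and -0.059 and the mesenchymal median to -0.21 and -0.17. The interferon list stood at -0.09. In all, 19 probe sets differed by 2-fold, 18 of them higher, and 3 of the 19 had a gene name. In the pooled limma model 0 probe sets passed, with 187 at an unadjusted p under 0.05. Leaving out the control of 4-week experiment 2 gave 17.

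The difference of the ethanol effect between 4 weeks and 1 week asks whether genes responded differently with time. The metallothionein list stood lower at 4 weeks than at 1 week (median difference -0.54), and the interferon (0.41) and unfolded protein (0.49) lists higher. MT1F had a difference of -1.25 ± 0.39 (4 weeks minus 1 week) and MT2A -0.94 ± 0.41. IFI6 had a difference of 2.79 ± 0.59, OAS1 1.41 ± 0.44, CCL22 1.59 ± 0.39 and CYP1A1 1.33 ± 0.34. HPGD had -1.58 ± 0.30 and CENPF, a kinetochore gene, -1.21 ± 0.38. Limma passed 0 probe sets with 177 at an unadjusted p under 0.05. The simulated test of this contrast called 0 of the probe sets changed by 1 or 2 log2 units. Only 200 probe sets were changed there, and the adjusted threshold depends on how many change. The simulation therefore does not show whether such changes could be called in the real arrays. Larger changes, such as that of IFI6, were not simulated. The difference of IFI6 was 3.27 without the control of 4-week experiment 2 and 2.30 without that of 4-week experiment 1. Of the 24 lists, 17 were called at the preset correlation, 0 with an estimated correlation and 0 by fry.

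Acetaldehyde is the first oxidation product of ethanol, and its array asks which genes differ after 1 week in 2.5 mM of it. Against the 1-week control, the adhesion genes CEACAM5 (log2 ratio 4.31) and CEACAM6 (3.29), the lysosomal glycoprotein gene GPNMB (3.73) and PDK4 (3.15), which inhibits pyruvate dehydrogenase, were higher. The sterol sensor INSIG1 (-3.28), the desaturase SCD (-2.94) and STC1 (-3.12), a secreted regulator of calcium and phosphate, were lower. The proliferation list had a median of -1.10, the cholesterol list -1.40 and the hypoxia list -0.90. These arrays belong to different processing sets, and 1321 probe sets differed by 2-fold, 791 higher and 530 lower. On the deposited scale the median of all log2 ratios was -0.35 against -0.02 after quantile normalization, and the split became 270 higher and 1122 lower. The untreated ratio control, of the same set as the acetaldehyde array, differed from the 1-week control in the same way: CEACAM5 by 4.07, INSIG1 by -3.42, the cholesterol list by -1.35, the hypoxia list by -1.16 and the proliferation list by -0.79. Of the 1321 probe sets, 991 (75%) differed by 2-fold the same way between these untreated arrays. Both ratios are over the 1-week control, which makes them overlap without any effect. Simulated ratios with no effect and a shared control gave an overlap of 20.8%, but with a mean of 103 2-fold probe sets. The simulated spread was thus smaller than the real one, and 20.8% is not the value to hold against the 75%. Between the ratio control and the 1-week ethanol array, neither of them part of the acetaldehyde ratio, 743 (56.2%) did, against 2.65% for independent ratios.

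Against the ratio control, the array of its own processing set, the acetaldehyde array showed fewer differences. Among the lowest ratios were PSAT1, of serine synthesis, at -1.21 and the cystine transporter gene SLC7A11 at -1.12. In the same fixed list as PSAT1, the serine synthesis gene PHGDH at -0.82, the asparagine synthetase ASNS at -0.70 and the stress regulator ATF4 at -0.66 were short of 2-fold. The matrix protein gene MGP was at -1.22. NDRG1 was higher at 1.27, BCAS1, a gene amplified in breast tumours, at 0.95 and P4HA1 at 0.78. The unfolded protein and amino acid list had a median of -0.18 with 5 of 29 genes higher, the proliferation list -0.29 with 3 of 39 higher, the hypoxia list 0.21 with 18 of 25 higher and the mesenchymal list 0.24 with 8 of 9 higher. The first pair lay at percentile 0 of random lists, the hypoxia list at 100 and the mesenchymal list at 99.8. Markers of other cell types stood higher too, 4 of 4 fibroblast and endothelial markers with a median of 0.15 and 2 of 2 blood cell markers with 0.38. With median centring the hypoxia median was 0.069 and the mesenchymal median to 0.10. CEACAM5 differed by 0.24, GPNMB by 0.07 and INSIG1 by 0.14. In all, 31 probe sets differed by 2-fold, 6 higher and 25 lower, and 8 had a gene name. Their correlation over probe sets was 0.994, against 0.971 between the acetaldehyde array and the 1-week control.

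In the pooled limma model, 41 probe sets passed for acetaldehyde against the 1-week control (27 higher, 14 lower, 3281 at an unadjusted p under 0.05) and 0 against the ratio control (177 at an unadjusted p under 0.05). The genes that passed against the 1-week control included BCAS1 (3.27 ± 0.32), STC1 (-3.12 ± 0.31), the aryl hydrocarbon receptor gene AHR (-2.72 ± 0.30) and the acetate-activating enzyme ACSS2 (-2.17 ± 0.23), each with an adjusted p of 0.0447. These calls depend on the processing. On the deposited scale, with median centring and with the larger pseudocount, 0 probe sets passed. The count was also 0 with no filter, with the stricter filter and with no intensity trend. The call rests on the arrays: from 264 to 2099 probe sets passed when 1 of the 4-week arrays was left out, the most without the control of experiment 1 and the fewest without the ethanol array of experiment 2.

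Acetaldehyde and ethanol were compared at 1 week at different doses and in different processing sets. Metallothioneins were lower than in the ethanol array, MT1X by a log2 ratio of -1.37 and MT2A by -1.11, with a list median of -0.62. Against untreated arrays the acetaldehyde array had list medians of -0.04 (1-week control) and -0.10 (ratio control). The difference of the list median thus lies in the high values of the ethanol array. This did not hold for every member: MT1E, at -0.94 against ethanol, stood at -0.64 against the 1-week control and -0.16 against the ratio control. CEACAM5 (4.24) and PGR (2.67) were higher, and INSIG1 (-3.04) and CDC20 (-2.43), an activator of the anaphase-promoting complex, lower. The proliferation list had a median of -1.14 and the cholesterol list -1.30. In all, 1113 probe sets differed by 2-fold, 552 higher and 561 lower, with 167 higher and 1290 lower on the deposited scale. The pooled limma model passed 0, with 2710 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0631, which does not show that the compounds act alike.

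Agreement between experiments was taken across 16648 probe sets, which are not independent replicates. The log2 ratios of the 4-week experiments correlated at r = 0.264 (rho 0.226), with the same sign in 57.4%, and at 0.141 with no filter on dim probe sets. They correlated about as well with the ratio between the untreated ratio control and 1-week control, with which they share no array, at 0.258 for experiment 1 and 0.207 for experiment 2. The 1-week ethanol ratios correlated with those of 4-week experiment 1 at -0.139 and of experiment 2 at 0.033. The 1-week ethanol and acetaldehyde ratios correlated at 0.354, but they share a control, which makes ratios correlate without any effect. Simulated ratios with no effect gave 0.5, a value set by giving every array the same spread. The real log2 ratios had SDs of 0.205 for ethanol and 0.582 for acetaldehyde, so 0.5 is not the value to hold against 0.354. With the ratio control as the control of acetaldehyde, so that no array is shared, r was -0.446 with the same sign in 33.6%. Each of these ratios is 1 array over 1 array. The value therefore cannot tell opposite effects of the compounds from differences between single arrays, and the cause was not tested.

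MCF-12A and untreated MCF-7 were compared to ask how the non-malignant line differs. Basal keratins, desmosomal cadherins and laminins were higher in MCF-12A, with a part of the mesenchymal genes. The oestrogen receptor gene, a part of its targets, GATA3 and most luminal markers were lower. A part of the cytokine, aldo-keto reductase and metallothionein genes was also higher in MCF-12A. The MCF-12A array was processed with 1 of the 4 MCF-7 arrays, and the lines grew in different media.

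Of 18 basal and myoepithelial markers with a probe set, 14 passed the filter. All 14 lay higher when adjusted over the list alone, 13 over all probe sets, with a median log2 fold change of 4.20. The keratin KRT5 was 6.78 ± 0.38 higher (n = 1 and 4 arrays; limma adjusted p = 1.38e-06), the desmosomal cadherins DSC3 and DSG3 5.73 ± 0.25 and 5.59 ± 0.31, and the laminin chain LAMB3 4.48 ± 0.33. Of 19 luminal markers 14 were lower and 1 higher (15 lower adjusted over the list alone), with a median of -2.50. The 1 higher, named after its values were seen, was the keratin KRT7 (3.63 ± 0.50; adjusted p = 0.00102). The oestrogen-induced secreted factor TFF1 was -5.77 ± 0.38, the transcription factor GATA3 -4.27 ± 0.32, the luminal keratin KRT19 -5.01 ± 0.34 and XBP1 -3.12 ± 0.27. Of 33 oestrogen targets 14 were lower (18 adjusted over the list alone), among them GREB1 (-4.07 ± 0.47), with a median of -1.30. ESR1 was -2.50 ± 0.52 (adjusted p = 0.0167) and lost its call without the filter on dim probe sets. PGR was -2.28 ± 0.89 and did not pass (adjusted p = 0.235), but it passed without the 1-week control (adjusted p = 0.00484).

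**Figure D3:**
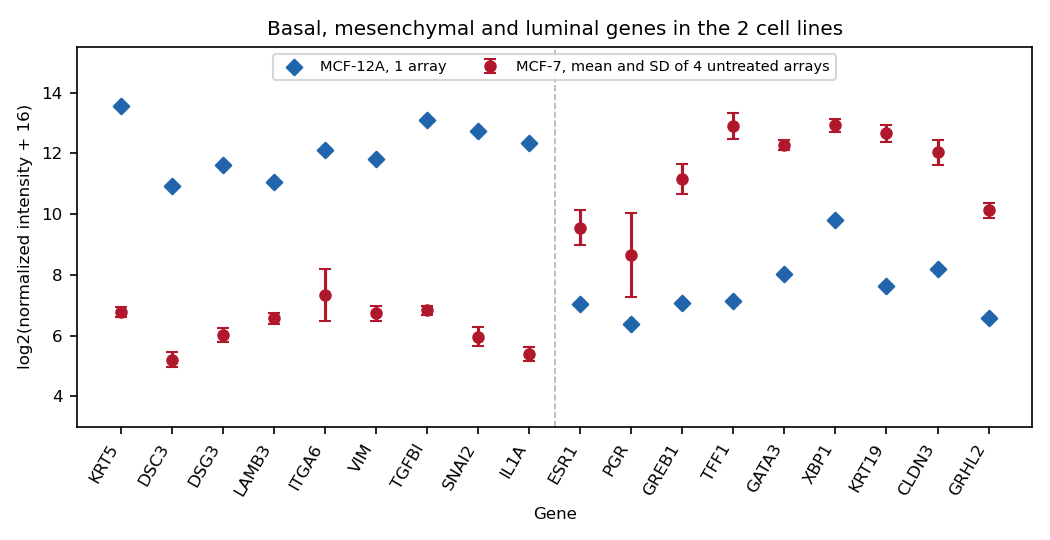
Log2(normalized intensity + 16) (vertical axis) of basal, mesenchymal and luminal genes (horizontal axis) in the MCF-12A array and in the 4 untreated MCF-7 arrays, shown as mean and SD. KRT5, 6.78 higher in MCF-12A, and TFF1, -5.77, lie far apart between the lines, and PGR, which did not pass, has a wide SD in MCF-7.

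Of 29 mesenchymal genes with a probe set, 14 passed the filter. The filter used the mean of the 2 lines' means, so a gene dim in 1 line passed only if bright enough in the other. These 14 genes had a median of 1.34, with 7 called higher in MCF-12A (7 adjusted over the list alone). Among them were the transcription factor SNAI2 by 6.78 ± 0.35, the matrix protein TGFBI by 6.28 ± 0.38 and vimentin, VIM, by 5.07 ± 0.37. Epithelial junction genes had a median of -0.83, with 6 of 21 lower (7 adjusted over the list alone). The tight junction gene CLDN3 was -3.83 ± 0.40, the epithelial regulator GRHL2 -3.55 ± 0.42 and E-cadherin, CDH1, -1.95 ± 0.29, whose call was lost with median centring. Matrix metalloproteinase genes MMP14 (4.36 ± 0.35) and MMP2 (2.61 ± 0.29) were higher, as were the basal stem cell markers CD44 (3.17 ± 0.57) and ITGA6 (4.77 ± 0.63), the Notch ligand JAG1 (3.24 ± 0.37) and NOTCH1 (2.56 ± 0.45). The p53 target FAS was 1.88 ± 0.31 higher, in a list with a median of 0.66 and 4 of 22 called (7 adjusted over the list alone), and lost its call on the deposited scale.

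A part of the cytokine, oxidative stress and metallothionein genes was higher as well. The cytokine genes IL1A (6.95 ± 0.28) and IL1B (3.53 ± 0.25) led an NF-kB list with a median of 1.16 and 5 of 10 called (5 adjusted over the list alone). The aldo-keto reductases AKR1B10 (5.72 ± 0.29), AKR1C1 (4.91 ± 0.49) and AKR1C3 (4.61 ± 0.31), which reduce aldehydes and steroids, led the oxidative stress list, with a median of 1.00 and 9 of 25 called (10 adjusted over the list alone). The metallothionein MT1E was 4.34 ± 0.41 higher, and its list had a median of 1.15 with 4 of 9 called (6 adjusted over the list alone). With an estimated correlation the NF-kB list had an adjusted p of 0.159, and the oxidative stress and metallothionein lists 0.113. The other stress lists were not called: the unfolded protein list had a median of -0.31 with 19 of 28 genes lower (adjusted p = 0.109) and the heat shock list 0.09 with 10 of 16 higher (adjusted p = 0.0862). Both were called without the control of 4-week experiment 1 (-0.48 and 0.13). The immediate early gene DUSP1, a phosphatase of stress kinases, was 3.80 ± 0.61 higher, in a list with a median of 1.53. Markers of blood cells passed the filter for 4 of 13 genes with a probe set, with a median of 1.91, LAPTM5 at 2.89 ± 0.26 and CD14 at 1.52 ± 0.31. The call of CD14 was lost on the deposited scale and that of the list without the filter on dim probe sets. The interferon list had a median of -0.02, with SAMD9 higher (2.60 ± 0.33) and IFITM1 lower (-2.68 ± 0.56), and its sign changed on the deposited scale, without the filter and without the 1-week control (0.075). IFITM1 lost its call without the filter. The proliferation list had a median of -0.38 (adjusted p = 0.052), and -0.63 and a call without the ratio control. MKI67 stood at -0.38 ± 0.73, and at 0.092 without the control of 4-week experiment 1. The highest change of a named gene was that of SNORD116-14, a small nucleolar RNA of an imprinted region, at 7.19 ± 0.19. Others were LDHB, a lactate dehydrogenase chain, at 6.54 ± 0.32, and FBP1, of gluconeogenesis, at -5.08 ± 0.37.

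Of 16647 probe sets 880 passed, 599 higher and 281 lower in MCF-12A, with 2597 at an unadjusted p under 0.05. The count was 1455 without the 1-week control. Against the ratio control alone, 2375 probe sets differed by 2-fold, 1239 higher and 1136 lower. Of the 24 lists, 12 were called at the preset correlation, among them basal markers (adjusted p = 1.1e-22; adjusted p = 0.10 with an estimated correlation), luminal markers (adjusted p = 4.5e-18; adjusted p = 0.11 with an estimated correlation) and oestrogen targets (adjusted p = 2.9e-12; adjusted p = 0.16 with an estimated correlation). With an estimated correlation 0 lists were called, and fry called 10.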

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

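The tests of explanations given here were all chosen after the results they bear on had been seen. The comparison of the ethanol effect at 4 weeks with that at 1 week was planned, and its adjusted p-values are those of camera at the preset correlation.

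For 17 lists the ethanol effect at 4 weeks differed from that at 1 week at the preset correlation, and for 0 with an estimated correlation. The difference of the effect (4 weeks minus 1 week, median log2) was 0.413 for the interferon response list (adjusted p = 1.2e-07), 0.487 for the unfolded protein and amino acid response (adjusted p = 3.07e-09), -0.546 for proliferation (adjusted p = 4.45e-14), 0.311 for hypoxia and glycolysis (adjusted p = 3.63e-06), 0.35 for mesenchymal genes (adjusted p = 3.77e-05) and -0.537 for metallothioneins (adjusted p = 0.00122). Smaller differences were 0.332 for stem cell genes, 0.238 for metalloproteinases and their inhibitors and -0.313 for cholesterol and lipid synthesis (adjusted p = 0.0104 each). Luminal markers stood at 0.108 (adjusted p = 0.025), basal markers at 0.24 and immediate early genes at 0.192 (adjusted p = 0.0381 each), and 2 blood cell markers at 0.774 (adjusted p = 0.0336). Junction genes stood at 0.14, NF-kB and cytokine genes at 0.295, p53 targets at 0.115 and ribosomal proteins at 0.091 (adjusted p = 0.0435 each). With an estimated correlation each of these lists had an adjusted p of 0.464 or 0.578. The sign of 6 lists turned under an alternative: junction genes (-0.013), ribosomal proteins (-0.047), cholesterol synthesis (0.094) and immediate early genes (-0.082) without the control of 4-week experiment 1, NF-kB genes (-0.26) at the 70th percentile filter and p53 targets (-0.0087) with median centring. The 1-week side of every difference is a single pair of arrays.

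The oxidative phosphorylation list had 1 array apart among the 4 untreated MCF-7 arrays: the ratio control lay away from the others by 0.896 of the whole range of the list's mean level, past Dixon's 95% critical value for 4 samples. Chance gives such a gap in about 1 in 20 groups, and 24 lists were tested.

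Interferon genes were higher with ethanol in both 4-week experiments. The choice among the 3 scalings did not account for this, since the lowest median over both experiments and these scalings was 0.24. Within the 4-week pairs the scalings hardly differed, so the test decides little about array scaling. The median of all log2 ratios was 0.007 after quantile normalization and 0.016 on the deposited scale in experiment 1, and -0.005 and -0.006 in experiment 2. Processing before deposit is common to all 3 scalings and was not tested. A change that goes with slower growth cannot be told apart: in experiment 2 the interferon list lay at the 100th percentile of random lists, but the proliferation list lay at percentile 0 there, with a median of -0.13. Nor can variation between cultures: the smaller of the shifts was 1.63 times the range of the list over 4 untreated arrays. These untreated arrays come from different processing sets, so that range includes differences of processing. The ethanol treatment itself stays among the open explanations and was not tested apart from these.

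Unfolded protein genes were higher and proliferation genes lower with ethanol in 4-week experiment 1. In experiment 2 the unfolded protein median was 0.05, and the proliferation median -0.13 with 0 of 39 genes higher. The untreated array of experiment 1 lay outside the range of the other 3 untreated arrays by 0.571 log2 units for the unfolded protein list and by 0.311 for the proliferation list, and the ethanol array by 0.0826 and 0. The other 3 arrays belong to other processing sets, so the state of that control culture cannot be told from a difference of processing. That state is a candidate explanation for part of this pattern, and an ethanol effect on top of it stays open.

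Cholesterol synthesis and hypoxia lists differed between the acetaldehyde array and the 1-week control. An acetaldehyde effect of this size was argued against, since 31 probe sets differed by 2-fold from the untreated array of the same processing set. A difference between the array sets that is there without acetaldehyde was in keeping with the values: 56.2% of the 2-fold probe sets differed by 2-fold in the same direction between the ratio control and the 1-week ethanol array, which are both outside that ratio, against 2.65% if the ratios were independent. What made the array sets differ, such as culture density, passage or processing, was not tested.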

How the results depend on the processing

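The ratio control in place of the 1-week control, and probe sets listed with a gene alone, were chosen after the data were seen; the other alternatives were planned. Where an array left out leaves a group with 1, that array is assumed to vary like the others. The cause of a change was not tested unless it is given.

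Interferon genes with ethanol at 4 weeks: the count of probe sets stayed at 0 under every alternative that kept all 4 arrays, with the experiment as a replicate block too, where 16 lists were called. Leaving out an array gave 0 to 332 probe sets and 9 to 16 lists. Over 3 experiments the count was 0 without the replicate block (16 lists) and with duration in place of the replicate block (12 lists), and 0 to 10 probe sets and 8 to 16 lists with an experiment left out. For the difference between 4 weeks and 1 week it was 0 with the replicate block (16 lists), 0 to 108 probe sets and 11 to 16 lists with an array left out, and 10 lists with no filter. For all 3, an estimated correlation and fry called 0 lists. The 1-week ethanol test gave 0 to 17.

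Acetaldehyde against the 1-week control in the pooled test gave 0 on the deposited scale, with median centring, pseudocount 64, no filter, the 70th percentile, no trend and the ratio control, 91 with probe sets listed with a gene (fewer tests), and 264 to 2099 with an array left out. Its 2-fold count was 865 at the 70th percentile (fewer tested), 372 against the mean of the untreated arrays, 4167 at 1.5-fold and 31 against the ratio control, where INSIG1 changed sign to 0.14 and SCD to 0.067. Against ethanol it was 3664 at 1.5-fold. The 1-week ethanol 2-fold count was 8 on the deposited scale, 10 with median centring, 5 with pseudocount 64, 63 with no filter, 5 at the 70th percentile, 3 with probe sets listed with a gene, 245 against the mean of the untreated arrays and 220 at 1.5-fold. The 4-week ratios correlated at 0.141 with no filter.

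MCF-12A: 540 probe sets passed at the 70th percentile, 2902 with all 8 MCF-7 arrays, 2375 differed by 2-fold from the named control, and 694 to 1455 passed with an array left out, with 12 to 14 lists. An estimated correlation called 0 lists. Of 58 named genes, 45 kept direction and call under every alternative. The interferon list changed sign to 0.0064 on the deposited scale and 0.13 with no filter, and ranged from -0.10 to 0.075 with an array left out; MKI67 ranged from -0.66 to 0.092.

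Other changes of sign: p53 targets, 4 weeks minus 1 week, -0.0087 with median centring; NF-kB genes, 4 weeks minus 1 week, -0.26 at the 70th percentile; ethanol metabolism at 4 weeks, -0.0079 at the 70th percentile. With an array left out at 4 weeks, ESR1 ranged from -0.18 to 0.065, TFF1 from -0.41 to 0.61, ADH5 from -0.13 to 0.058, MKI67 from -1.16 to 0.042, the oestrogen list from -0.027 to 0.079 and the ethanol metabolism list from -0.024 to 0.097. For 4 weeks minus 1 week, junction genes ranged from -0.013 to 0.32, cholesterol synthesis from -0.57 to 0.094, ribosomal proteins from -0.047 to 0.24 and immediate early genes from -0.082 to 0.33. The unfolded protein list over 3 experiments ranged from -0.015 to 0.52. The array signal over background limits dim genes, whose log2 ratios depend on the added 16.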

Other observations

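The tests between untreated arrays and the other groupings of the 6 arrays were chosen after the data had been seen.

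Untreated MCF-7 arrays of the 4-week experiments (2) and the 1-week experiment (1) differed in metabolic genes. Hypoxia and glycolysis genes were lower in the 4-week controls, with a list median of -1.28 and 0 of 25 genes higher, 16 lower past the test over all probe sets and 19 adjusted over the list alone. ALDOC, a glycolytic aldolase, was -4.18 ± 0.34, NDRG1 -3.62 ± 0.56 and the lipid droplet gene HILPDA -2.38 ± 0.29. Cholesterol and lipid synthesis genes had a median of -0.96, with 10 lower (11 adjusted over the list alone), the fatty acid synthase FASN at -2.68 ± 0.35 and the sterol sensor INSIG1 at -2.37 ± 0.50. PGR was 2.21 ± 0.34 higher, the adhesion gene NRCAM 3.79 ± 0.40, GPNMB 2.99 ± 0.38 and CYP24A1, which degrades vitamin D, 2.58 ± 0.23. Mesenchymal genes had a median of -0.61, with 1 of 9 higher and 5 lower past the test (5 adjusted over the list alone). Markers of other cell types went the same way, with 0 of 4 fibroblast and endothelial markers higher (median -0.54, 2 lower past the test) and 0 of 2 blood cell markers (median -1.11, both lower past the test). Proliferation genes had a median of 0.41, with 10 higher (9 adjusted over the list alone) and CENPF at 2.61 ± 0.26. In limma, 4072 probe sets passed (2066 higher, 2006 lower), from 3302 to 6142 with 1 array left out, and 0 with no filter on dim probe sets. With an estimated correlation the hypoxia, cholesterol, mesenchymal and proliferation lists each had an adjusted p of 0.84. The arrays come from different processing sets, so culture and processing cannot be separated.

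Ethanol and control arrays of the 3 experiments can be grouped in 10 ways, too few for a share under 0.05. The real grouping called 0 probe sets in limma, a count that all 10 groupings reach by construction, so it says nothing about chance, and the highest other was 1517. At an unadjusted p under 0.05 the real grouping gave 520, 6 of 10 gave at least as many, and the highest other was 4250. Of the lists 13 were called, 4 of 10 groupings gave at least as many, and the highest other was 16. With experiment as a term, the 6 groupings that part 1 pair alone are 3 fits of a single pair, each counted in duplicate, so they are not comparable with the real one. The 1517 calls, 4250 probe sets and 15 lists come from the pair of 4-week experiment 1, whose arrays differ more than those of the other pairs. Among the 4 groupings that part all 3 pairs, the real one gave 520 and the others 214, 488 and 1019, with 13 lists against 10, 8 and 16.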
